A study of Homo sapiens with 4 samples.

How the data were processed

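RNA was sequenced from 4 cultures of 2 human liver cancer cell lines, HepG2 and PLC/PRF/5, each as an untreated control at 24 h and after 24 h with 20 uM PF-429242. Per the labels' protocols, total RNA was isolated with a phenol-based kit, checked for quality on a Bioanalyzer and made into libraries with standard Illumina reagents. Whether transcripts were selected by polyadenylation or ribosomal RNA was depleted, and whether the libraries kept strand, is not given in the sources used here.

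The deposited values were FPKM, fragments per kilobase of gene scaled to the fragments counted in the library, for 32479 Ensembl genes in each of the 4 libraries. Per the submitters' processing notes, reads were aligned with TopHat2 to the genome build GRCh38. The version of TopHat2, the counting program, the annotation release and the program that made the FPKM values are not given in the sources used here. Groups were taken from the labels, with 1 library in each of the 4 groups and no library left out. Of the gene identifiers, 32273 were in the table of gene names used here, 25231 of them with a symbol. Gene positions are those of GENCODE release 29 on GRCh38, which held 32354 of the identifiers.

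Depth was recovered from the FPKM values themselves. With gene lengths taken as the union of exons in GENCODE 29, the values of 24452 genes (75.3%) were whole multiples of 1 fragment within a tolerance of 0.001. For 7619 further genes the ratios between libraries gave whole fragments, and 408 genes, none above 0.451 FPKM, were left unsolved. The recovered totals were 16722204 fragments in the HepG2 control, 20350701 in treated HepG2, 21387301 in the PLC/PRF/5 control and 16982560 in treated PLC/PRF/5. For a gene of 1 kb, 3 fragments then correspond to 0.179, 0.147, 0.140 and 0.177 FPKM in these libraries. Ratios of FPKM between a pair of libraries are given with 95% intervals from the exact conditional binomial (Clopper-Pearson) test of the recovered fragments. These intervals cover counting error only, and compare libraries, not conditions, since fragments without molecular identifiers need not be independent molecules. Where a library had 0 fragments, the limit was computed from 3 fragments in that library.

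For each line, and for HepG2 over PLC/PRF/5 among the controls, the log2 ratio of (FPKM + 1) was computed on the deposited scale. The pseudocount of 1 understates the change of low genes. Genes with at least 1 FPKM in either library were counted as higher or lower at 2-fold or more, with no p-value. A shared effect of treatment was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), with the cell line as a block, for the 12838 genes with at least 1 FPKM in at least 2 libraries. Its p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. This fit has 1 residual degree of freedom, its replicates are the 2 lines, and its spread is the difference in response between them. Correlations of the lines' log2 ratios are across genes, which are not independent replicates, and carry no p-value.

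For 26 of 29 gene lists, the median log2 ratio of the measured members (at least 1 FPKM in at least 2 libraries, which may both be of the other line) was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The other lists, markers of fibroblasts, endothelial cells and blood cells, had too few measured members. The percentile describes these libraries and is not a p-value. In the shared fit, each list's p-values were also adjusted over the list alone. The genes named were fixed by rule. They were the 10 highest and 10 lowest log2 ratios in each line and between the controls, the 5 largest differences between the lines in each direction, every member of the list of site-1 protease and its substrates, and up to 4 members of every other list with the largest mean change. Because small RNA genes with few fragments filled much of the first of these, the 15 highest and 15 lowest nuclear protein-coding genes with at least 100 fragments were added after the values were seen. Other genes named outside these rules were also chosen after their values were seen. A few genes that the rules select are not reported here one by one; they stay in the counts and list medians. The lists, thresholds, comparisons, naming rule and first set of alternatives were chosen before the data were examined.

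This first set held pseudocounts of 0.1 and 5, no filter on low values or at least 5 FPKM, thresholds of 1.5-fold and 4-fold, rescaling to equal sums of FPKM (TPM scale), median-of-ratios scaling, quantile normalization, limma without trend, with robust moderation or without the cell line block, and an adjusted p under 0.10. Added after the data were seen were at least 20 fragments, totals over nuclear genes alone, limma-voom on the recovered fragments, counts without mitochondrial and RRP genes, and 4 further gene lists. Other scalings moved the median log2 ratio of all genes by more than 0.1. The shift was 0.17 in HepG2 and 0.13 in PLC/PRF/5 under median-of-ratios scaling, 0.18 and 0.12 under quantile normalization, 0.17 and 0.11 with nuclear totals, and -0.31 and -0.30 on the TPM scale. List medians are therefore also read relative to the median of all 12838 measured genes, -0.16 in HepG2 and -0.12 in PLC/PRF/5.

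The procedure was tested on simulated tables drawn from the real libraries' means and totals. In these, 200 genes were changed 4-fold or 8-fold, by the same factor in both lines. They were drawn from nuclear protein-coding genes outside the fixed lists with at least 5 FPKM in each line. Their calls therefore do not cover low genes or small RNA genes. The 14 housekeeping genes were lowered 2-fold in treated HepG2 alone. The spread of the shared fit is the difference in response between the lines. Its simulated calls therefore do not show how many genes it finds where the lines respond differently. With counting error alone, 100% of these 200 genes passed 2-fold in each line at both sizes and 100% were called by the shared fit. Of unchanged genes the fit called 21, among 13102 genes fitted, and 41 among 13061 with a dispersion of 0.01. The housekeeping genes counted as unchanged in the fit, but were left out of the counts per line and intervals that follow. Of unchanged genes, 207 of 12002 in HepG2 and 178 of 12659 in PLC/PRF/5 passed 2-fold, of which 9 and 2 had at least 20 fragments. Intervals held the true ratio for 95.5% and 95.3% of genes, and for 61.0% and 60.9% once that dispersion was added, so the intervals are too narrow for variation between cultures. Fragments were recovered exactly for 31984 of 32071 simulated genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.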

Results

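Gene expression was compared with and without PF-429242 in HepG2, a human hepatoblastoma-derived cell line, and PLC/PRF/5, a human hepatoma line that carries integrated hepatitis B virus DNA. PF-429242 is a small-molecule inhibitor of site-1 protease (MBTPS1), the Golgi enzyme that cleaves the sterol regulatory element-binding proteins (SREBPs), ATF6 and related membrane-bound transcription factors so that they can enter the nucleus. Each of the 4 groups held 1 library, so no difference between a treated library and its control had a replicate check, and none of these is given a p-value. The libraries held 16722204 counted fragments (HepG2 control), 20350701 (HepG2 with PF-429242), 21387301 (PLC/PRF/5 control) and 16982560 (PLC/PRF/5 with PF-429242). Between 11428 and 12441 genes reached 1 FPKM per library. The mitochondrial genome took 16.6% of the fragments in the HepG2 control (95% exact Clopper-Pearson interval 16.61 to 16.65) and 27.6% in treated HepG2 (27.58 to 27.62). It took 21.3% in the PLC/PRF/5 control (21.30 to 21.34) and 28.2% in treated PLC/PRF/5 (28.17 to 28.21). This last share includes 13 adjacent mitochondrial genes that were far lower in that library alone, so the rises of the lines cannot be compared directly. Mitochondrial ribosomal RNA went from 2.59% to 4.90% of fragments in HepG2 and from 3.26% to 0.447% in PLC/PRF/5. The rest of the mitochondrial genome went from 14.0% to 22.7% and from 18.1% to 27.7%. The median log2 ratio over genes with at least 1 FPKM was -0.17 in HepG2 and -0.13 in PLC/PRF/5.

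The question in HepG2 was which transcripts differ after 24 h of site-1 protease inhibition. Treated HepG2 cells had far lower levels of the transcripts of cholesterol synthesis, and lower levels of those of cholesterol uptake. Sterol methyl oxidase MSMO1 (chromosome 4, 165327623 to 165343160) went from 70.4 to 5.57 FPKM, a ratio of 0.0791 (95% counting interval 0.0703 to 0.0887). Squalene epoxidase SQLE stood at 70.7 FPKM in the control and 9.94 with PF-429242, and HMGCS1, which makes the pathway's HMG-CoA, at 38.0 and 5.18 FPKM.

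All 20 cholesterol synthesis genes were lower in treated HepG2, 19 of them by 2-fold or more, with a median log2 ratio of -2.02 that lay at percentile 0 of matched random lists. Beside MSMO1, the log2 ratio was -3.04 for the isoprenoid isomerase IDI1, -2.71 for SQLE, -2.66 for HMGCS1, -2.56 for MVD and -2.55 for DHCR7. PMVK, a mevalonate pathway kinase, was the member nearest to 0, at -0.22. The 9 genes of cholesterol uptake and sterol sensing had a median of -0.82 (percentile 0; -0.95 without INSIG1, which had 1 and 0 fragments in HepG2), 4 of them lower by 2-fold or more, including the sterol carrier STARD4 at -1.91. The 18 genes of fatty acid and triglyceride synthesis had a median of -1.05 (percentile 0), with 10 lower by 2-fold or more. Among these, the stearoyl-CoA desaturase SCD (chromosome 10, 100347124 to 100364834) was at 419 FPKM in the control and 69.4 with PF-429242 (ratio 0.166, 0.162 to 0.170), the fatty acid synthase FASN at 106 and 35.0 FPKM, and the desaturases FADS1 and FADS2 had log2 ratios of -2.07 and -2.29.

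The transcript of the drug's target did not differ detectably: MBTPS1 (chromosome 16, 84053761 to 84116906) was at 13.0 FPKM in control and 13.4 in treated HepG2 (ratio 1.03, 0.978 to 1.09). Of the 12 measured genes of the list of site-1 protease and its membrane-bound substrates, 2 were lower by 2-fold or more, the SREBP genes themselves. SREBF2 (chromosome 22, 41833079 to 41907308), which encodes SREBP-2, was at 20.7 and 3.32 FPKM (ratio 0.160, 0.145 to 0.176), and SREBF1 at 6.54 and 1.98 FPKM. The log2 ratios of the others were -0.23 for MBTPS2, which encodes site-2 protease, -0.22 for the SREBP escort SCAP, -0.13 for ATF6, -0.09 for ATF6B, -0.42 for CREB3, 0.02 for CREB3L2, -0.08 for CREB3L3, -0.33 for CREB3L4 and -0.37 for GNPTAB. CREB3L1 was listed at 0 in both HepG2 libraries. The median of the list was -0.22 (percentile 20.1).

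Genes with higher levels in treated HepG2 were fewer. IGFBP1 (chromosome 7, 45888357 to 45893668), a secreted binding protein of insulin-like growth factors, was at 17.8 FPKM in the control and 108 with PF-429242 (ratio 6.05, 5.503 to 6.66). DEPP1 (chromosome 10, 44970981 to 44978810), a gene induced by FOXO transcription factors, was at 3.19 and 16.8 FPKM (ratio 5.27, 4.46 to 6.27). CYP1A1 (chromosome 15, 74719542 to 74725610), the classic target of the aryl hydrocarbon receptor, was at 1.94 and 7.62 FPKM (ratio 3.93, 3.19 to 4.87). The 20 measured genes of ATF4 and the integrated stress response had a median of 0.50 (percentile 100), with 19 above 0. The cystine transporter gene SLC7A11 and the mTOR inhibitor gene DDIT4 were both at 1.14, NUPR1 at 0.93 and STC2 at 0.72. The 17 ER chaperones and ATF6 targets moved the other way, with a median of -0.46 (percentile 0; -0.26 under median-of-ratios scaling) and 16 below 0. The calcium-binding chaperone gene CALR was at 460 and 200 FPKM (ratio 0.434, 0.424 to 0.444), MANF at -0.88 and HSP90B1 at -0.61 on the log2 scale. The 13 genes of the XBP1-driven secretory pathway lay close to all genes, with a median of -0.07 (0.09 relative to all measured genes, percentile 98.8, and 0.13 under median-of-ratios scaling), and of these the Golgi-to-ER receptor gene KDELR3 was at -1.19.

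Proliferation genes were modestly lower in treated HepG2. The 20 mitosis genes, all below 0, had a median of -0.38 (percentile 0; -0.18 under median-of-ratios scaling), with CDK1 at -0.64 and TOP2A at -0.55, and the 20 DNA replication genes, also all below 0, a median of -0.37 (percentile 0; -0.18 under that scaling), with TK1 at -0.76. The 7 metallothioneins, near-identical genes that may share reads, had a median of -0.73 (percentile 0), and MT1G was at 37.7 FPKM in the control and 17.6 with PF-429242. The 17 p53 targets had a median of -0.32 (percentile 0.25). Lists placed high relative to all genes were bile acid and drug metabolism (9 genes, median 0.08, percentile 99.9), hypoxia and glycolysis (13 genes, 0.04, percentile 99.97), NRF2 and oxidative stress (13 genes, -0.02, percentile 99.9) and autophagy (12 genes, -0.04, percentile 99.4). These medians are near 0 on the deposited scale. The sign turned on the TPM scale for the first pair (-0.21, and -0.29 with 15 hypoxia members measured). It turned under median-of-ratios scaling for NRF2 (0.093, percentile 95.3) and autophagy (0.15). The percentile of autophagy was 97.3 after quantile normalization. The 10 inflammatory and NF-kB targets had a median of -0.05 whose percentile was 97.6 on the deposited scale, 40.1 with a pseudocount of 0.1 and 36.0 under median-of-ratios scaling, and the 7 of them that reached 1 FPKM in HepG2 had a median of -0.30. Within the hypoxia list the directions differed, since the glycolytic enzyme gene ALDOC was at -1.37 and the glucose transporter gene SLC2A1 at 0.23. The 12 mitochondrially encoded genes had a median of 0.70 (percentile 100), which was 0.00 after quantile normalization. That scaling gives genes of equal rank the same value. It therefore removes a change shared by the highest genes and does not bear on this one.

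For the remaining lists in HepG2, medians were -0.22 for 22 hepatocyte secreted proteins and transcription factors (percentile 16.0), -0.10 for 7 acute phase genes (71.8), -0.12 for 20 lysosome genes (93.6) and -0.27 for 7 LXR targets (6.73). They were -0.18 for 4 interferon-stimulated genes (percentile 51.6), -0.24 for 13 epithelial-mesenchymal and matrix genes (10.98) and -0.19 for 12 genes of fatty acid oxidation and ketogenesis (36.2). Medians were 0.06 for 3 CREB3L3 targets and hepatokines (93.3) and -0.21 for 14 housekeeping genes (21.8). On the TPM scale, where 5 CREB3L3 targets and hepatokines passed the filter, their median was -0.78 at percentile 2.125. Single members stood out in some of these lists: the lysosomal acid lipase gene LIPA was at 21.0 and 9.19 FPKM, the keratin gene KRT19 at 26.1 and 11.5 FPKM and the lipid droplet gene PLIN2 at 41.3 and 62.3 FPKM. Of the markers of other cell types, no fibroblast gene reached 1 FPKM in at least 2 libraries. The endothelial marker PECAM1 was at 0.857 and 0.819 FPKM in HepG2, and of the blood cell markers LYZ alone was measured, at 504 and 462 FPKM.

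In all, 124 genes were higher and 264 lower by 2-fold or more among 12347 genes in HepG2. Of these, 7 and 65 were protein-coding and 98 and 159 belonged to small RNA classes, in which mitochondrial tRNA and ribosomal RNA genes were counted. The 10 highest log2 ratios were those of IGFBP1, DEPP1, the mitochondrial tRNA genes MT-TW (4 and 41 fragments) and MT-TF (0 and 10 fragments), and 6 nuclear small RNA genes with at most 7 fragments, among them MIR4771-2, MIR924, MIR10B and RNU6-601P. The 10 lowest included MSMO1, IDI1, SQLE, HMGCS1, SCD, MVD, DHCR7 and the microRNA gene MIR1206 (5 and 0 fragments). With at least 20 fragments required, the counts were 17 higher and 79 lower. The share of higher genes among those past 2-fold was 31.96% on the deposited scale, 44.8% under median-of-ratios scaling, 47.4% after quantile normalization and 43.9% with totals over nuclear genes.

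**Figure D1:**
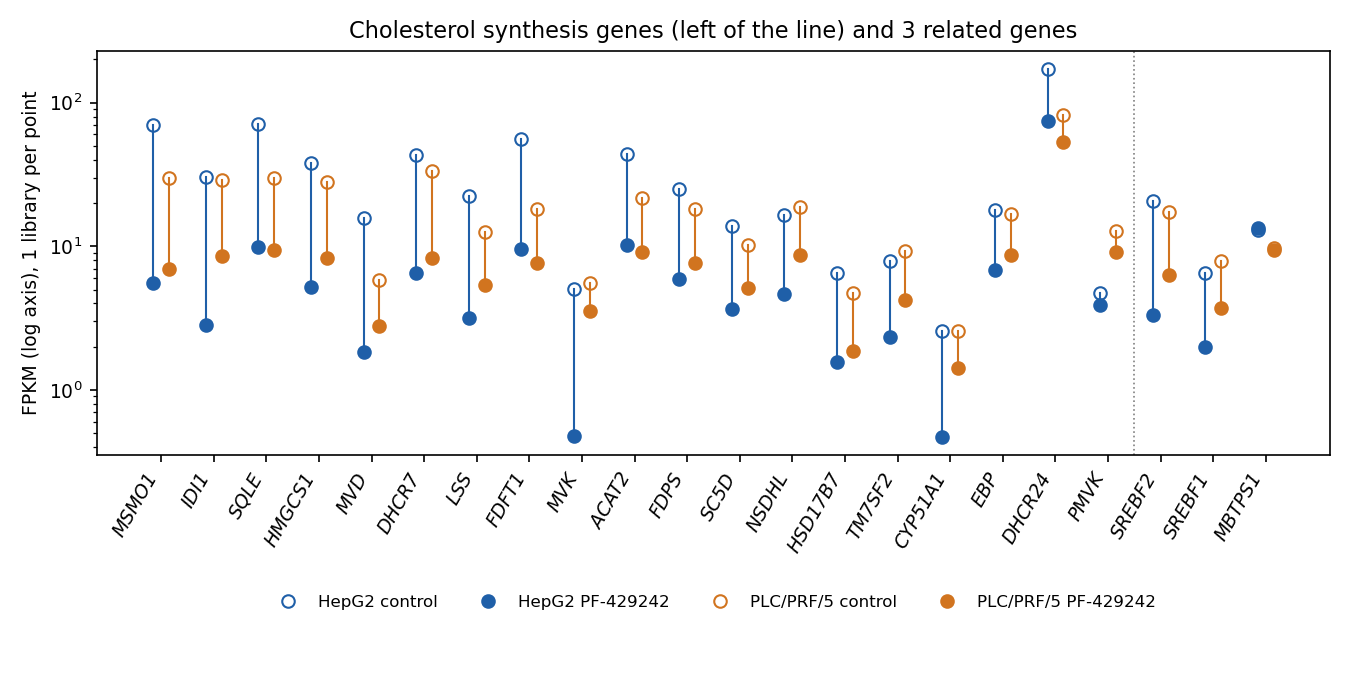
FPKM (log axis) of 19 of the 20 cholesterol synthesis genes and of SREBF2, SREBF1 and MBTPS1, with 1 point per library, open for control and filled for PF-429242, HepG2 in blue and PLC/PRF/5 in orange. Every cholesterol synthesis gene shown was lower with PF-429242 in both lines, while MBTPS1 stayed between 9.38 and 13.4 FPKM.

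The same question was asked in PLC/PRF/5, where the sterol genes were again lower with PF-429242. MSMO1 was at 29.8 FPKM in the control and 6.90 with PF-429242 (ratio 0.231, 0.205 to 0.260), SQLE at 29.8 and 9.49 and HMGCS1 at 28.1 and 8.29. INSIG1, which retains SCAP in the ER, was at 16.6 and 3.57 FPKM (ratio 0.215, 0.185 to 0.248). All 20 cholesterol synthesis genes were lower, 12 by 2-fold or more, with a median of -1.06 (percentile 0). Of these, DHCR7 was at -1.90, IDI1 at -1.66 and HMGCS1 at -1.65 on the log2 scale.

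Cholesterol uptake and sterol sensing had a median of -0.63 in PLC/PRF/5 (percentile 0, 4 of 9 lower by 2-fold or more), and fatty acid and triglyceride synthesis -0.67 (percentile 0, 3 of 18). SCD was at 296 and 63.6 FPKM (ratio 0.215, 0.209 to 0.221), FASN at 59.2 and 26.5 and FADS1 at 31.8 and 9.87. MBTPS1 was at 9.70 and 9.38 FPKM (ratio 0.967, 0.906 to 1.03), SREBF2 at 17.4 and 6.34 (ratio 0.366, 0.338 to 0.395) and SREBF1 at 7.95 and 3.70. The log2 ratios of the remaining members of the site-1 protease list were -0.52 for MBTPS2, -0.02 for SCAP, -0.04 for ATF6, -0.20 for ATF6B, -0.35 for CREB3, 0.13 for CREB3L2, -0.23 for CREB3L3, -0.03 for CREB3L4 and -0.43 for GNPTAB, and CREB3L1 was at 0.915 and 0.700 FPKM. The list median was -0.21 (percentile 10.8).

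Among genes with higher levels in treated PLC/PRF/5, DEPP1 was at 2.45 and 11.9 FPKM (ratio 4.85, 4.06 to 5.82), CYP1A1 at 13.6 and 35.0 (ratio 2.57, 2.38 to 2.77), IGFBP1 at 230 and 494 (ratio 2.14, 2.08 to 2.202) and BMF, which encodes a proapoptotic BH3-only protein, at 1.23 and 4.29 (ratio 3.50, 2.88 to 4.26). The steroid sulfotransferase gene SULT2A1 was at 5.94 and 16.2 FPKM, osteopontin (SPP1) at 16.8 and 40.6, and the hepcidin gene HAMP at 1.68 and 4.57. The list of ATF4 and the integrated stress response had a median of 0.45 (percentile 100), with all 20 measured genes above 0, NUPR1 at 0.80, STC2 at 0.70 and SLC7A11 at 0.60. Bile acid and drug metabolism had a median of 0.37 (percentile 99.99), with CYP27A1 at 0.97, the bile acid-induced repressor gene NR0B2 at 0.97 and the drug efflux pump gene ABCB1 at 0.92. NRF2 and oxidative stress genes had a median of 0.33 (percentile 100), with the aldo-keto reductase gene AKR1C1 at 1.04. The p53 targets had a median of 0.21 (percentile 100), with 15 of 17 above 0, the opposite sign to HepG2, but -0.073 on the TPM scale. Hepatocyte secreted proteins and transcription factors had a median of 0.03 (percentile 99.8; -0.29 on the TPM scale) with members on both sides, AHSG at 0.98 and the fibrinogen gene FGB at -0.90.

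ER chaperones and ATF6 targets were lower in PLC/PRF/5 too, at a median of -0.31 (percentile 0.095, 16 of 17 below 0; -0.16 under median-of-ratios scaling), with CALR at -0.52, PDIA4 at -0.39 and MANF at -0.06. Mitosis genes had a median of -0.33 (percentile 0, 19 of 20 below 0; -0.18 under that scaling), with CDK1 at -0.56, and DNA replication genes one of -0.23 (percentile 2.49, 19 of 20 below 0), which was -0.084 (percentile 3.60) under median-of-ratios scaling. Inflammatory and NF-kB targets had a median of -0.33 (percentile 0.36), with the chemokine genes CXCL1 at -0.85 and CXCL8 at -0.41. The remaining medians were 0.02 for LXR targets (percentile 90.1), -0.11 for the XBP1-driven secretory pathway (63.9), 0.32 for CREB3L3 targets and hepatokines (97.55; 96.9 with a pseudocount of 5 and 97.2 under median-of-ratios scaling), -0.01 for autophagy (94.0), -0.17 for lysosome (25.3) and 0.07 for acute phase (93.9). They were -0.20 for interferon-stimulated genes (percentile 24.7), -0.01 for epithelial-mesenchymal and matrix genes (94.7), -0.07 for hypoxia and glycolysis (76.2), 0.07 for metallothioneins (95.2), -0.12 for fatty acid oxidation and ketogenesis (54.5) and -0.22 for housekeeping genes (7.82). Some lists held members below 1 FPKM in both PLC/PRF/5 libraries: without these, medians were 0.47 for 5 acute phase genes, 0.26 for 2 metallothioneins, 0.65 for 8 genes of bile acid and drug metabolism, 0.69 for 2 CREB3L3 targets and -0.0026 for 6 LXR targets. PECAM1 was at 1.36 and 1.03 FPKM and LYZ at 179 and 209 FPKM in PLC/PRF/5.

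**Figure D2:**
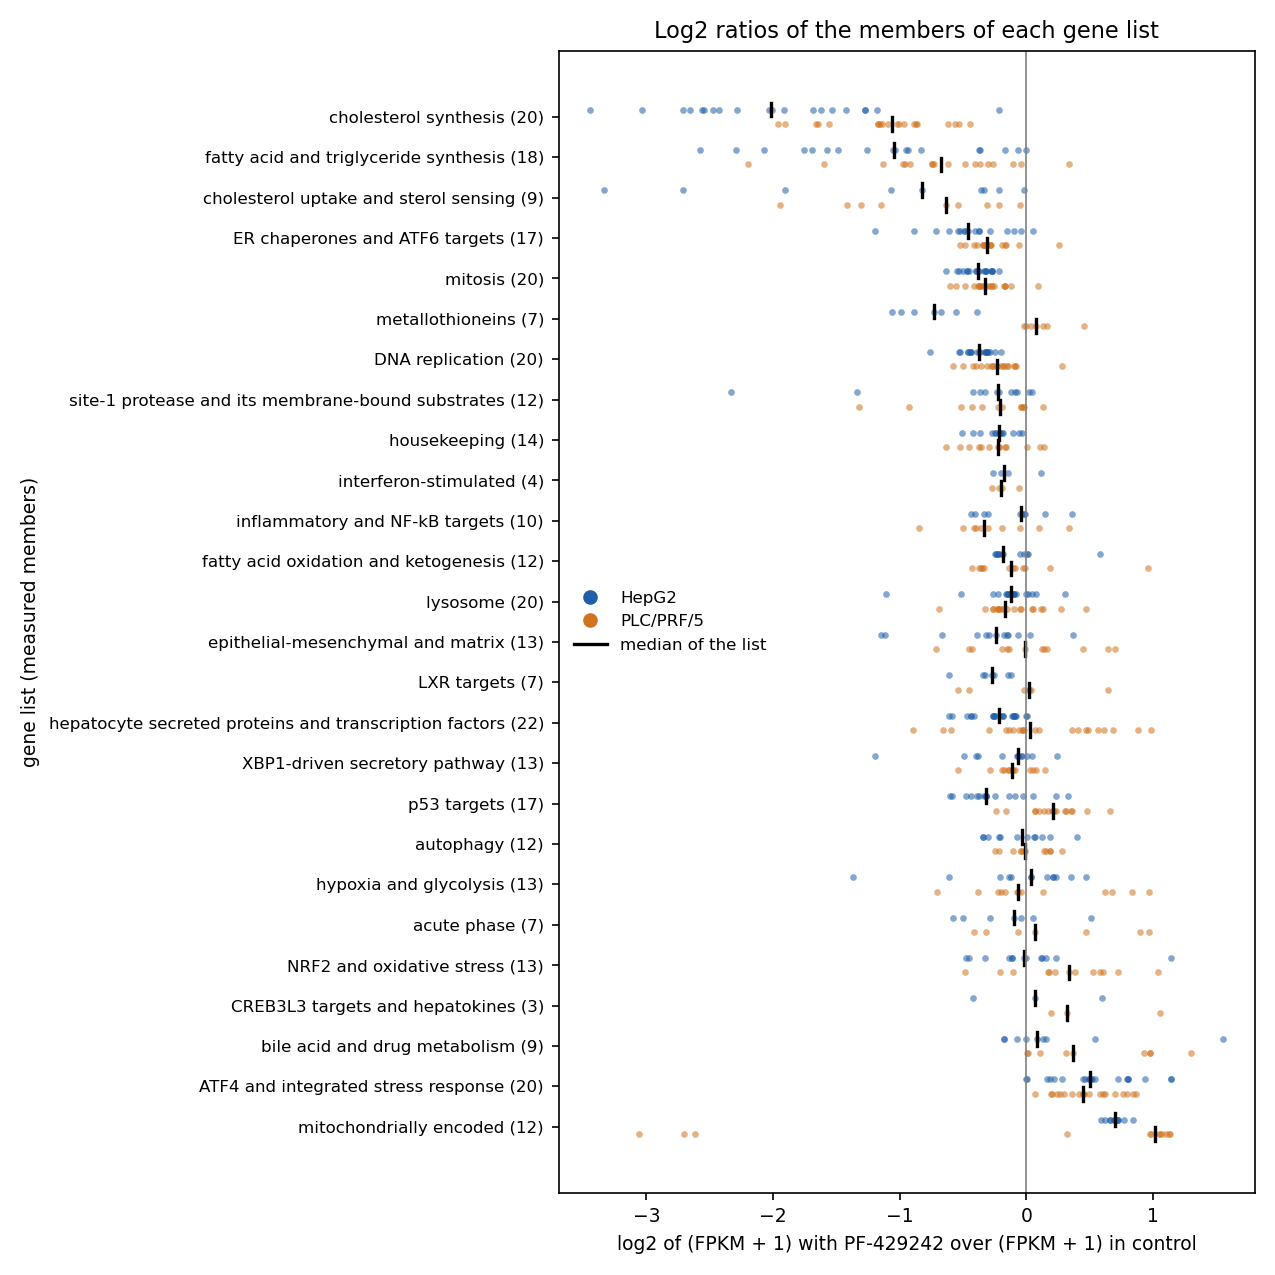
Log2 ratio of (FPKM + 1), PF-429242 over control, of every measured member of 26 gene lists (points; HepG2 in blue, PLC/PRF/5 in orange) with the list's median (black bar), and the number of measured members in brackets. Cholesterol synthesis has the lowest medians (-2.02 and -1.06) and the mitochondrially encoded genes the highest (0.70 and 1.01), with 3 of the latter far below 0 in PLC/PRF/5.

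A pair of transcript sets were lower in the treated PLC/PRF/5 library alone. The 12 mitochondrially encoded protein-coding genes of the fixed list had a median of 1.01 in PLC/PRF/5 (percentile 100), 6 of them higher by 2-fold or more, but MT-ND5, MT-ND6 and MT-CYB were lower, at 8671 and 1415, 9580 and 1150, and 11525 and 1768 FPKM in control and treated cells. The mitochondrial ribosomal RNA genes were lower too, at ratios of 0.145 for MT-RNR1 and 0.136 for MT-RNR2. MT-TH went from 527 fragments to 0, at least 139-fold lower, MT-TV from 156 to 0 (at least 41.3-fold lower), MT-TT from 138 to 0 (at least 36.5-fold lower), MT-TE from 298 to 1, MT-TS2 from 167 to 3, MT-TL2 from 107 to 3 and MT-TL1 from 1313 to 84. Of 31 mitochondrial genes with at least 50 fragments in the control, the 13 that were lower by 2-fold or more lay side by side on the circular genome, from MT-TH (start 12138) through the origin to MT-TL1 (end 3304). Their median log2 ratio was -3.61 in PLC/PRF/5 and 0.68 in HepG2. MT-ND4 (10760 to 12137), which adjoins MT-TH, had a ratio of 1.25 in PLC/PRF/5. The other protein-coding genes outside the stretch had ratios of 1.97 to 2.19.

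The other set held the 8 genes with symbols beginning in RRP, which act in ribosomal RNA processing and were grouped after their values were seen. Together they had 9986 fragments in the PLC/PRF/5 control and 811 in the treated library, at ratios between 0.0719 and 0.146. RRP1B (chromosome 21, 43659548 to 43696079) was at 25.2 and 1.86 FPKM and RRP36 at 30.2 and 3.92. Their median log2 ratio was -2.33 in PLC/PRF/5 and -0.15 in HepG2. EMG1, a ribosome biogenesis methyltransferase, was at 7.77 and 1.26 FPKM and FTSJ1, a tRNA methyltransferase, at 16.0 and 4.37.

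In all, 194 genes were higher and 239 lower by 2-fold or more among 13144 genes in PLC/PRF/5. Of these, 18 and 40 were protein-coding, 135 and 154 belonged to small RNA classes, and 10 and 13 lay on the mitochondrial genome. These counts overlap. The mitochondrial genes are also counted by class, with their tRNA and ribosomal RNA genes placed in the small RNA classes. The 10 highest log2 ratios were those of DEPP1, MT-TS1 (10 and 42 fragments) and 8 small RNA genes with at most 6 fragments, among them MIR5587, MIR4677, MIR1205, MIR326 and RNU7-45P. The 10 lowest were MT-TH, MT-TE, MT-TV, MT-TT, MT-TS2, MT-TL2, MT-TL1, MT-ND6, RRP1B and the ribosomal RNA gene RNA5-8SN1 (23 and 0 fragments). Without mitochondrial and RRP genes, 184 were higher and 218 lower, and with at least 20 fragments, 36 and 70. The share of higher genes among those past 2-fold was 44.8% on the deposited scale, 56.3% under median-of-ratios scaling, 53.6% after quantile normalization, 55.2% with totals over nuclear genes and 28.7% on the TPM scale.

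**Figure D3:**
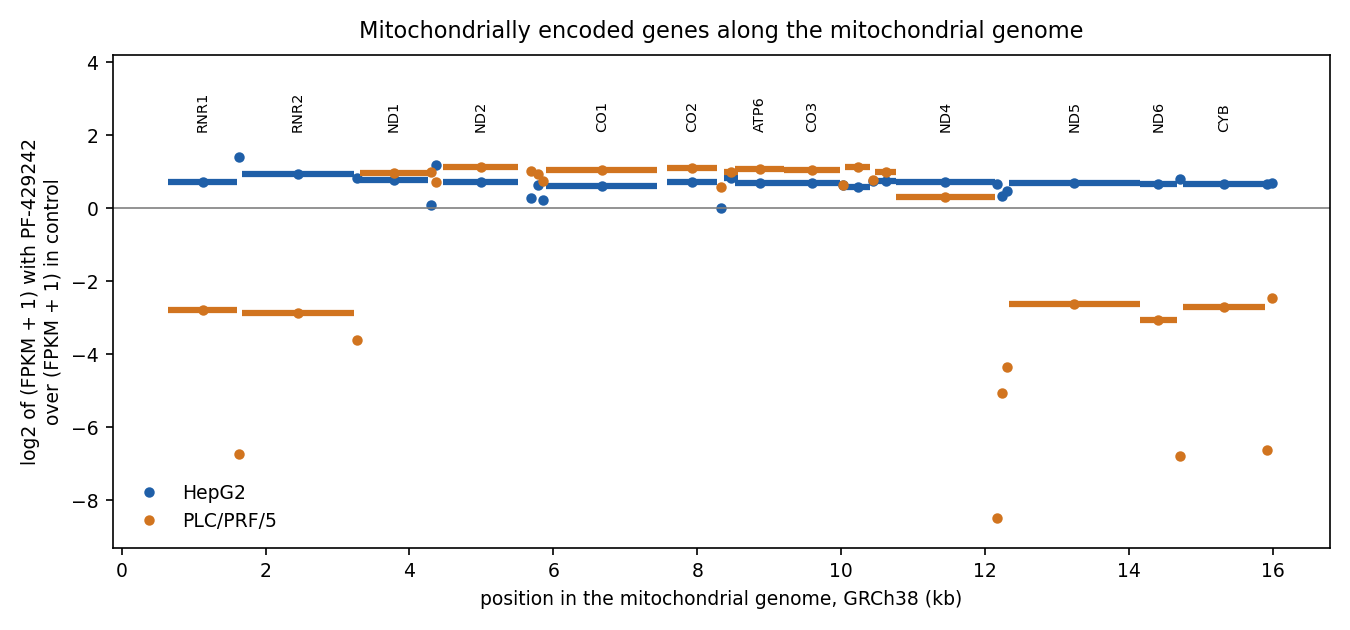
Log2 ratio of (FPKM + 1), PF-429242 over control, of the 31 mitochondrial genes with at least 50 fragments in the PLC/PRF/5 control, against position in the mitochondrial genome of GRCh38 (kb); each bar spans a gene, with HepG2 in blue and PLC/PRF/5 in orange. In PLC/PRF/5, 13 adjacent genes around the origin had a median of -3.61, while the genes outside this stretch had a median of 0.99.

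A fit over both lines asked which genes responded alike. Every cholesterol synthesis gene was lower in both, and 20 of 20 fell in the limma fit when adjusted over the list alone (lowest adjusted p 0.00380). Mean log2 ratios over the lines were -2.70 ± 0.37 (SE) for MSMO1 and -2.23 ± 0.17 for DHCR7. Adjusted over the list alone, 13 of 18 genes of fatty acid and triglyceride synthesis fell, with SCD at -2.39 ± 0.12. So did 6 of 9 genes of cholesterol uptake and sterol sensing (4 under median-of-ratios scaling, 8 on the TPM scale). Of the site-1 protease list 4 of 12 fell (2 under median-of-ratios scaling, 11 of 13 on the TPM scale). In the list of ATF4 and the integrated stress response 16 of 20 rose (17 under median-of-ratios scaling, 0 of 21 on the TPM scale), with SLC7A11 at 0.87 ± 0.15 and INHBE, a hepatokine gene outside the list, at 0.87 ± 0.09. In bile acid and drug metabolism 2 of 9 rose (1 on the TPM scale, 0 without the cell line block), with CYP1A1 at 1.42 ± 0.10. Of 3 CREB3L3 targets and hepatokines 1 rose, and 0 did without the cell line block, nor did any of 5 measured on the TPM scale. Of 12 genes of fatty acid oxidation and ketogenesis 1 rose, and 0 did with a pseudocount of 0.1, without the trend or without the block; 1 rose and 3 fell with limma-voom, and 1 rose and 7 of 13 fell on the TPM scale. Of genes outside all lists, DEPP1 was at 1.99 ± 0.10.

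Smaller shifts also passed over single lists: 17 of 20 mitosis genes, 12 of 20 DNA replication genes and 11 of 17 ER chaperones and ATF6 targets fell when adjusted over the list alone. None of these 3 lists kept a call under median-of-ratios scaling, quantile normalization or nuclear totals, or without the trend or the cell line block. Likewise 3 of 22 hepatocyte genes, 2 of 7 LXR targets, 2 of 10 inflammatory genes and 2 of 14 housekeeping genes fell, and none did under those 3 scalings. Of 20 lysosome genes 1 fell, and 0 did with a pseudocount of 0.1 or 5, without the trend or without the block. Under those 3 scalings 1 lysosome gene rose and 1 fell, and 15 fell on the TPM scale. On the deposited scale, in the fit described above, no member passed in the lists of the XBP1-driven secretory pathway, autophagy, p53 targets, acute phase, interferon-stimulated genes, epithelial-mesenchymal and matrix genes, hypoxia and glycolysis, NRF2 and oxidative stress, metallothioneins or mitochondrially encoded genes. Some of these did pass under alternatives. Of 12 mitochondrially encoded genes, 9 rose without the trend and with limma-voom and 8 with robust moderation, and of 13 NRF2 genes 4 rose under the 3 scalings. On the TPM scale 11 of 13 genes of the XBP1-driven pathway fell, as did 5 of 15 of hypoxia and glycolysis and 5 of 13 epithelial-mesenchymal genes. Under the 3 scalings, by contrast, 2 of 13 hypoxia genes rose and 1 fell, and 1 of 13 epithelial-mesenchymal genes rose.

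Over all 12838 genes, limma called 0 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.193. At an unadjusted p under 0.05, 244 genes were higher and 2244 lower, 2488 in all, against 1384 under median-of-ratios scaling, 1331 after quantile normalization, 1369 with nuclear totals and 112 without the block. Limma-voom on the recovered fragments also called 0, with 3135 at that level, and the TPM scale called 4987 of 16340 genes. Without the cell line block, the calls over single lists were 15 of 20 for cholesterol synthesis, 1 of 18 for fatty acid and triglyceride synthesis and 0 for the ATF4, uptake and site-1 protease lists. The treated PLC/PRF/5 library could not be left out, since no residual degree of freedom would remain.

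The responses of the lines shared their sterol genes but differed in size. Of the 20 cholesterol synthesis genes, 19 had a more negative log2 ratio in HepG2. Across 12838 genes the log2 ratios of the lines had a Pearson correlation of 0.162 and a Spearman correlation of 0.213. Without mitochondrial and RRP genes these were 0.211 and 0.213. Across 10304 protein-coding genes with at least 100 fragments, mitochondrial and RRP genes again left out, they were 0.373 and 0.262. Past 2-fold, 17 genes were higher in both lines, against 0.532 for independent lists of 67 and 102 genes, and 35 were lower in both, against 1.52 for lists of 155 and 126. Only 7 protein-coding genes were higher by 2-fold or more in HepG2, so most of the 17 were of other classes. The values 0.532 and 1.52 treat all genes as equally likely to pass 2-fold, whereas genes with few fragments pass more easily. Another 25 genes passed 2-fold in opposite directions. The 5 genes with the largest positive difference, HepG2 minus PLC/PRF/5, were MT-TH, MT-TE, MT-TV, MT-TT and MT-TS2, and the 5 with the largest negative difference were MIR1206, MIR6739, MIR4312, MIR7111 and RNU7-84P, all with at most 10 fragments in a library. Differences between the lines were not tested, since each has 1 library per group.

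**Figure D4:**
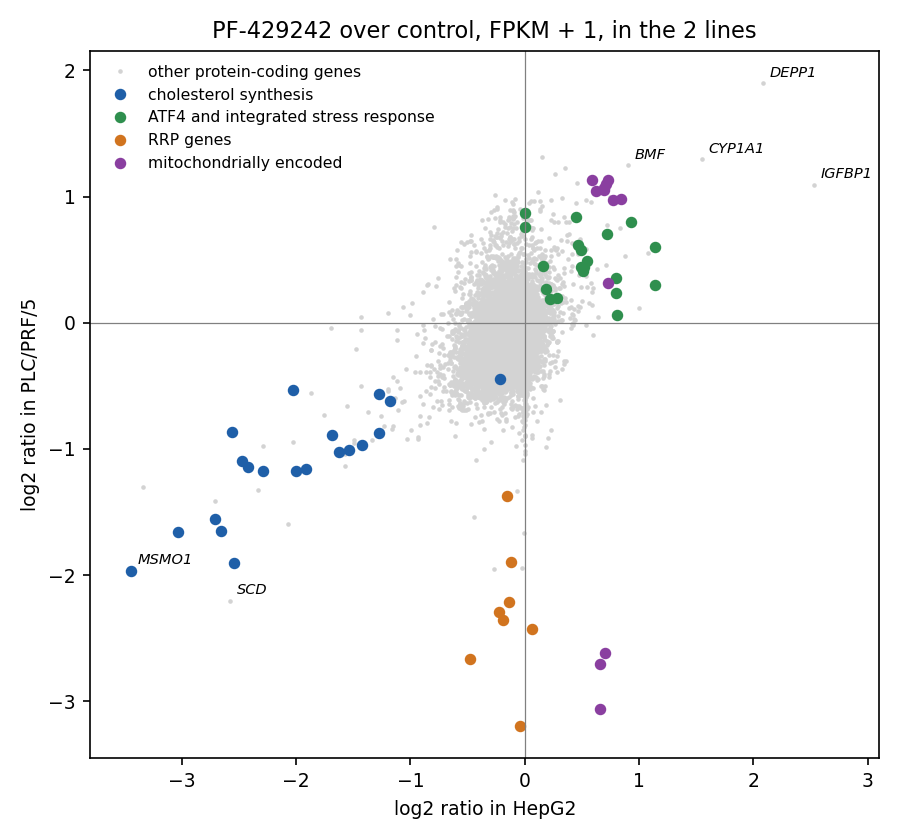
Log2 ratio of (FPKM + 1), PF-429242 over control, in HepG2 (horizontal axis) and PLC/PRF/5 (vertical axis) for protein-coding genes with at least 100 fragments in a library, with members of 4 gene lists in colour. Cholesterol synthesis genes lie below 0 in both lines (medians -2.02 and -1.06), ATF4 genes mostly above 0 (0.50 and 0.45), and RRP genes are low in PLC/PRF/5 alone (-2.33 against -0.15).

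The controls gave the baseline of the lines, which differed far more from each other than either did from its treated library. Fetal liver protein AFP was at 2976 FPKM in HepG2 and 288 in PLC/PRF/5, SPP1 at 210 and 16.8, the aldo-keto reductase AKR1B10 at 102 and 3.72 and the cartilage collagen gene COL2A1 at 23.3 and 0.126. In the other direction, the neuropeptide gene NTS was at 0.0385 FPKM in HepG2 and 915 in PLC/PRF/5, the glutathione transferase GSTP1 at 0.0939 and 313, the actin-binding thymosin gene TMSB4X at 0.878 and 331 and the long noncoding RNA UCA1 at 0.115 and 122. CRH and the gap junction gene GJA1 were listed at 0 in HepG2 and stood at 236 and 146 FPKM in PLC/PRF/5. MSMO1 and SQLE were also higher in the HepG2 control, at 70.4 against 29.8 and 70.7 against 29.8 FPKM.

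In all, 1391 genes were higher and 1812 lower by 2-fold or more in HepG2 among 13861 genes, 926 and 1286 of them protein-coding, with a median log2 ratio of -0.06. The other genes among the 10 highest were MT1G, MT1E, FREM1, IGDCC3, BPIFB2 and SLCO4C1. Among the 10 lowest were also MUC13 and the pseudogenes MTND1P23, MTCO2P12 and MTCO1P12, whose reads may come from near-identical mitochondrial genes. Those genes differed little between the controls, at HepG2 to PLC/PRF/5 ratios of 0.798 for MT-ND1, 0.798 for MT-CO2 and 0.884 for MT-CO1. Reads shared in equal proportion in both lines would therefore not account for the difference.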

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

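The tests of counting error in the RRP genes and both tests of the mitochondrial stretch were chosen only after the result was seen; the other tests were written down before their results, on patterns already noticed.

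In the treated PLC/PRF/5 library the genes of a stretch of the mitochondrial genome were far lower than in its control, while in HepG2 they were higher, and this opposite direction is what drew attention to them. The log2 ratio in HepG2 minus that in PLC/PRF/5 was 9.16 for MT-TH, 8.14 for MT-TV, 7.59 for MT-TE, 7.29 for MT-TT, 4.43 for MT-TL1, 3.72 for MT-ND6, 3.37 for MT-CYB and 3.32 for MT-ND5, and the differences were not tested. Lower RNA of the mitochondrial protein-coding genes as a whole is argued against by the 12 such genes of the fixed list, 3 of them in the stretch. Their median log2 ratio in PLC/PRF/5 was 1.01, with 9 above 0, which was already known when this test was chosen. The list leaves out the mitochondrial ribosomal RNA genes, which were lower, at ratios of 0.145 for MT-RNR1 and 0.136 for MT-RNR2. The genes lower by 2-fold or more formed 1 unbroken run along the circular genome, but that is how the pattern was noticed, so it does not test a loss of reads from a contiguous stretch. Whether the RNA of the stretch or only its reads were lost stays open, because 1 library shows it.

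The RRP genes were lower in the same library, by a median log2 ratio of -2.33, and were also grouped after they were seen. A lower ribosome biogenesis programme is argued against by 31 other genes of that process, at a median of -0.098 in PLC/PRF/5. Removal of reads of all protein-coding genes named for ribosomal RNA methylation or processing is argued against by 9 other measured genes listed as such. Their median was -0.153 (lowest -0.389). The methyltransferase genes EMG1 (-1.95), FTSJ1 (-1.66) and METTL25B (-1.33), outside that list, were lower too. With them the median of 12 genes was -0.256, so removal by a narrower choice of names stays open. The list holds no ribosomal RNA gene, so it does not bear on removal of ribosomal RNA reads themselves. The ribosomal RNA genes MT-RNR1, MT-RNR2 and RNA5-8SN1 were lower in that library. Counting error in the RRP genes is argued against by the highest upper bound of their ratios, 0.200. A candidate explanation left open and not tested is a step in that library that removed reads of particular sequences, the mitochondrial ribosomal RNA among them.

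Cholesterol synthesis genes were lowered more in HepG2 than in PLC/PRF/5, with a gap between the list medians of -0.957 (log2). The pseudocount is argued against by the gap of -1.08 with a pseudocount of 0.1. The gap was -0.948 under median-of-ratios scaling and -0.909 with totals over nuclear genes alone. These scalings moved the median of all genes by 0.17 and 0.17 in HepG2 and by 0.13 and 0.11 in PLC/PRF/5. Shifts so alike in the lines could change the gap only little. The choice among these scales therefore does not account for the gap, but they do not test any other effect of scaling or of removed reads. A difference between the lines in their response may account for the gap, as a hypothesis found and tested on the same data. MSMO1 and SQLE started higher in the HepG2 control and reached similar levels in both treated libraries, while HMGCS1 ended lower in treated HepG2. Whether a higher starting level in HepG2 accounts for part of the gap was not tested. With 1 library per group, a difference between single cultures in dose, density or handling stays open.

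The p53 targets had medians of opposite sign in the lines, with a median difference of -0.503 (HepG2 minus PLC/PRF/5), which was not tested.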

How the results depend on the processing

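At least 20 fragments, totals over nuclear genes, limma-voom and counts without mitochondrial and RRP genes were added after the data were seen; the other alternatives were planned. The cause of a change was not tested, except where the construction shows it: a larger pseudocount, minimum or fold threshold counts fewer genes, and the TPM scale raises all values relative to the pseudocount, but those of the treated libraries by less, which lowers the ratios before the pseudocount is added, since FPKM sums were larger with PF-429242 (443727 against 352221 in HepG2, 516958 against 409697 in PLC/PRF/5).

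With a pseudocount of 0.1, 239 genes were higher and 530 lower in HepG2, 447 and 484 in PLC/PRF/5, 2112 were higher between the controls, and 36 were higher and 75 lower in both lines. With a pseudocount of 5 these were 9 and 35, 18 and 36, 429 and 510 between the controls, and 4 and 9. With at least 5 FPKM they were 21 and 80, 38 and 61, 785 and 865, and 6 and 18. On the TPM scale they were 445 and 1280, 451 and 1119, 3204 and 2917, and 62 and 195, with 65 genes rising in the shared fit and 4922 genes falling in the shared fit. At 1.5-fold, the counts were 288 and 684, 559 and 666, and 2746 and 3283, and at 4-fold 6 and 26, 3 and 32, and 232 and 470. With at least 20 fragments, 17 and 79 genes passed in HepG2 and 36 and 70 in PLC/PRF/5. After quantile normalization 200 genes were higher in HepG2, and under median-of-ratios scaling 26 were higher in both lines.

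The Pearson correlation across genes between the lines was 0.0816 with a pseudocount of 0.1, 0.236 with 5, 0.277 with at least 5 FPKM and 0.103 on the TPM scale. The Spearman correlation across genes between the lines was 0.254 with a pseudocount of 5, 0.183 without a filter, 0.344 with at least 5 FPKM, 0.172 on the TPM scale, 0.266 under median-of-ratios scaling, 0.262 after quantile normalization and 0.264 with nuclear totals. The cholesterol synthesis median in HepG2 was -1.53 with a pseudocount of 5 and -2.54 on the TPM scale, and in PLC/PRF/5 it was -1.22 with 0.1, -0.78 with 5 and -1.47 on the TPM scale.

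Medians close to 0 turned sign. In HepG2, under median-of-ratios scaling, quantile normalization and nuclear totals, the XBP1-driven secretory pathway was at 0.13, 0.12 and 0.13, autophagy at 0.15, 0.10 and 0.15 (0.00079 without a filter), and NRF2 and oxidative stress at 0.093, 0.096 and 0.090. On the TPM scale, p53 targets in PLC/PRF/5 were at -0.073, hepatocyte genes in PLC/PRF/5 at -0.29 and bile acid and drug metabolism in HepG2 at -0.21. Hypoxia and glycolysis in HepG2 was at -0.29. CREB3L3 targets and hepatokines in HepG2, within the tails on the deposited scale, were at -0.78. The filter acts on the rescaled values, so these last 2 medians cover 15 and 5 members, against 13 and 3 on the deposited scale. Of 414 list medians under all alternatives, 41 turned sign, 14 of them medians beyond the tails of the random lists on the deposited scale. Of 4350 values of named genes, 4106 kept their side of 2-fold, 122 no longer reached it, 122 newly did and 0 passed 2-fold on the deposited scale and had the opposite sign; counted at any size, 349 turned sign. The fall of cholesterol synthesis genes over the list alone held for 15 to 20 genes under every alternative, and depth limits genes below about 20 fragments.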

Other observations

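All genes and lists in this part were chosen after the data were seen, apart from the fixed gene lists it refers to; the test of FOXO targets was written down before its result.

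Single genes lower by 2-fold or more in HepG2 with PF-429242 were the cholesterol transporter gene NPC1L1 at -1.87 (log2 ratio), TAGLN at -1.48, ACTA1, ANKRD1 and the fatty acid-binding protein gene FABP1 at -1.43 each, MYL9 at -1.16, CCN1 at -1.15 and the acyl-CoA-binding protein gene DBI at -1.03. They were picked one by one, and no theme among them was tested. The actin gene ACTB, a common reference transcript, was at 602 and 423 FPKM in HepG2 and 845 and 544 in PLC/PRF/5.

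DEPP1, IGFBP1 and BMF, higher in both treated lines, are known targets of FOXO transcription factors, which led to the hypothesis that FOXO targets are higher as a group. Of 18 other FOXO targets, 13 were measured, with medians of 0.01 in HepG2 and 0.15 in PLC/PRF/5. The lower of the lines' percentiles among matched random lists was 99.875, but the random lists were centred below 0, at -0.17 in HepG2 and -0.12 in PLC/PRF/5. In HepG2, 7 members were above 0 and 6 below, and 0 of 13 rose in the shared fit when adjusted over the list alone, so the hypothesis stays open. PPARGC1A (0.58 in HepG2 and 0.32 in PLC/PRF/5) and KLF15 (0.53 and 0.45) were the highest members on average over the lines, and INSR was at -0.10 in both.

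Some genes were listed at or close to 0 in a HepG2 library but not in PLC/PRF/5, and whether they are deleted, silent or missed in counting was not tested. INSIG1 had 1 fragment in the HepG2 control and 0 in the treated library, against 1296 and 221 in PLC/PRF/5. The malic enzyme gene ME1 and the pyruvate dehydrogenase kinase gene PDK4 were listed at 0 in the HepG2 control and stood at 27.2 and 19.5 FPKM in the PLC/PRF/5 control. CHAC1 had 0 fragments in the HepG2 control and 31 in the treated library, against 577 and 547. INSIG1, ME1 and PDK4 counted as measured members of their lists through PLC/PRF/5 alone, and without members under 1 FPKM in HepG2 the HepG2 medians were -0.95 for cholesterol uptake and sterol sensing and -1.06 for fatty acid and triglyceride synthesis.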
